A study of soil metagenome with 296 samples.

How the data were processed

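Soil DNA from 296 plots of the BioCON grassland experiment was measured on a GeoChip, a single-colour array whose probes target functional genes of soil microbes. The deposited table gives 1 intensity per probe and plot on a linear scale, from DNA labelled with Cy5 per the labels' protocols. Undetected probes are blank in that table, and no value was 0 or below. Array totals varied by a coefficient of variation of only 3.34%, and whether they had been scaled before deposition was not tested. The rule for detection and any earlier scaling are not given in the sources used here. The table also gives each probe a gene name, a category and, for most probes, the lineage of the source organism. All 296 arrays matched a labelled plot. Each array is a separate plot, so the replicates are plots and not repeated arrays of 1 sample. If CO2 was applied to field rings that hold several plots, the plots of a ring are not independent replicates for CO2, and every p for CO2 that treats them so is too small.

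Each array was scaled to the mean total signal of all arrays. A gene family was the set of probes with 1 gene name, its value was the log2 of their summed intensity, and undetected probes added nothing to a sum. Families with signal on at least 90% of the arrays and at least 3 probes were tested, which kept 393 of 491 families and left out 98. Changes are given as percent change of summed intensity with a 95% confidence interval, or on the log2 scale.

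Families were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment, threshold 0.05). All 296 arrays entered 1 fit with the 4 treatments and the plant species number as factors, with 289 residual degrees of freedom. The contrasts were CO2 at each N level, N at each CO2 level, both together, their interaction, and 16 against 1 plant species. A moderated F test asked whether treatment effects differed between species numbers. The same model was applied to the totals of 30 gene lists, of the table's own categories, domains and 22 phyla, and to single probes detected on at least 50% of the arrays (28649 of 55646). Of the 232 members written into the lists, 149 matched a gene name by letters and digits alone. Community composition was tested with adonis2 of vegan 2.7.1 on Bray-Curtis distances with 9999 permutations. Differences in detected probes and in Shannon diversity were tested with two-sided permutation tests (100000 resamples, labels moved within plant species number), which take no account of position, and by least squares with position blocks as a random block. Tables were read with the R package data.table (1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

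The contrasts, main tests, gene lists, most alternatives and the rule for named genes were chosen before the data were examined. Tests and alternatives added later are named as such below. For each contrast on families, the rule names the 10 largest rises and the 10 largest falls past the threshold, all of them if fewer passed, and the 5 smallest p-values if none passed. Within a described list it names the members that passed or, where none did, the member with the most probes. Names outside this rule are marked as chosen after their values were seen.

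The alternatives were scaling to the median log2 probe value, quantile normalization, no scaling, the mean log2 over detected probes in place of the sum, other filters, the number of detected probes as a covariate, and fits without 7 arrays over 3 scaled MADs from the median. Fits of subsets of plots and a replicate block were also planned. After the data were seen, a further alternative was added because arrays with nearby replicate numbers resembled each other. Plots were placed in 6 position blocks, made by dividing the replicate numbers of each group into 3 runs of nearby numbers at each CO2 level. These blocks lie inside 1 CO2 level each and are spread evenly over N and species number. For CO2 they therefore entered as a random block (duplicateCorrelation), and for N, the interaction and species number as a factor. What the replicate numbers stand for in the field or the laboratory is not given in the sources used here.

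The fits were tested on simulated data drawn from the real arrays for the CO2 contrast at ambient N. Over 393 families, 40.0% of changes of 0.05 on the log2 scale were recovered, 57.0% of changes of 0.1 and 85.0% of changes of 0.2, while 0.661% of unchanged families were called. Labels were moved freely between arrays in these draws, so the rates leave out position: splits of the position blocks other than that by CO2 called 22 to 246 families at ambient N. Over 28649 probes, in 1 draw, 34.3% of changes of 0.25 were recovered (23 of 67), 88.1% of changes of 0.5 (59 of 67) and 66 of 66 changes of 1. In that draw 152 of 28449 unchanged probes were also called (0.534%), so a large part of the probe calls there was false. The median 95% interval of a family's change reached 4.23% to either side, and 6.04% for the interaction. For CO2 these intervals leave out position and are too narrow if plots resemble one another by position. For the total of the Energy process category at ambient N, the standard error went from 0.00839 to 0.0226 on the log2 scale with position blocks as a random block.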

Results

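The plots formed 4 treatments of 74 plots each: ambient or elevated CO2 combined with ambient or elevated N. Within each treatment, 32 plots held 1 plant species, 15 held 4, another 15 held 9 and 12 held 16. The array table covered 55646 probes of 491 gene names in 13 categories. Between 14522 and 33178 probes gave a signal on an array (26.1% to 59.6%), with a median of 28435. The mean number of detected probes was 27604.5 ± 3188 (SD, n = 74) at ambient CO2 and N, 27800 ± 2186 under elevated CO2, 28579 ± 2150 under elevated N and 27974 ± 2172 under both. Bacterial probes carried 93.8% of the signal, fungal probes 3.55% and archaeal probes 1.80%.

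The first comparison asked how elevated CO2 shifted functional genes in plots at ambient N. Elevated CO2 went with less mauAB, which encodes methylamine dehydrogenase. Its share of array signal was 0.240% ± 0.0212 (SD, n = 74) at ambient CO2 and 0.224% ± 0.0195 (n = 74) at elevated CO2, a fitted change of -6.80% (95% interval -9.36 to -4.16, limma adjusted p = 0.000452), or -0.10 on the log2 scale, against -0.0336 with median scaling (adjusted p = 0.557). cydB, a subunit of the high-affinity terminal oxidase cytochrome bd, rose by 5.21% (2.45 to 8.03, adjusted p = 0.0257), from 0.141% ± 0.00983 to 0.148% ± 0.0133 of the signal, but changed by -0.0591 on the log2 scale when the mean log2 over detected probes replaced the sum. Of 393 families, 20 passed the threshold, 6 higher and 14 lower, and 90 had an unadjusted p under 0.05. The other rises were the phage contractile_central_tail_tube_protein (14.1%), Ni_Fe_hydrogenase for hydrogen turnover (9.17%), the SMR_antibiotics multidrug transporters (4.88%), the peroxide-removing reductase ahpC (3.13%) and the dissimilatory sulfite reductase subunit dsrB (2.93%), of which all but the phage family turned negative with that mean (-0.0569, -0.0318, -0.0425 and -0.0513 on the log2 scale).

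Among the falls, 4HBH fell by 6.27% (95% interval -9.58 to -2.83, limma adjusted p = 0.0285), which is -0.0934 on the log2 scale and became -0.0255 with median scaling (adjusted p = 0.620). The same adjusted p of 0.0285 held for 4 further families whose direction depended on the scaling. These were carA (carbazole dioxygenase, -4.37%), nitA (-4.14%), ohbAB (halobenzoate dioxygenase, -4.11%) and bphC (the ring-opening biphenyl dioxygenase, -3.81%), all of which turned slightly positive when arrays were scaled to the median probe. The vanillate demethylase gene vanA (-2.02%, adjusted p = 0.0401) and the xylose isomerase gene xylA (-2.68%, adjusted p = 0.0322) also fell, and both turned positive with median scaling. The assimilatory nitrite reductase NiR fell by 5.08% (adjusted p = 0.0401), from which median scaling left -0.00734 on the log2 scale (adjusted p = 0.903). Families with few probes moved most: formate_hydrogenlyase_complex by -21.5% (7 probes), the cobalt and nickel efflux gene cnrA by -14.0% (4 probes) and the phage integrase_tyrosine by -11.6% (13 probes). The herbicide and chlorophenol degradation genes atzB (-3.58%, limma adjusted p = 0.0328) and pcpE (-3.73%, adjusted p = 0.0380) complete the 20, both turned positive with median scaling, and both were chosen after their values were seen. With the 6 position blocks as a random block none of the 393 families passed, and the adjusted p was 0.998 for mauAB, for cydB and for each of the other 16 families named by the rule. The split also depended on scaling, with 3 higher and 0 lower after median scaling (0 of the 20 among them), 28 higher and 5 lower without scaling (11 of the 20 among them), and 0 calls after quantile normalization.

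**Figure D1:**
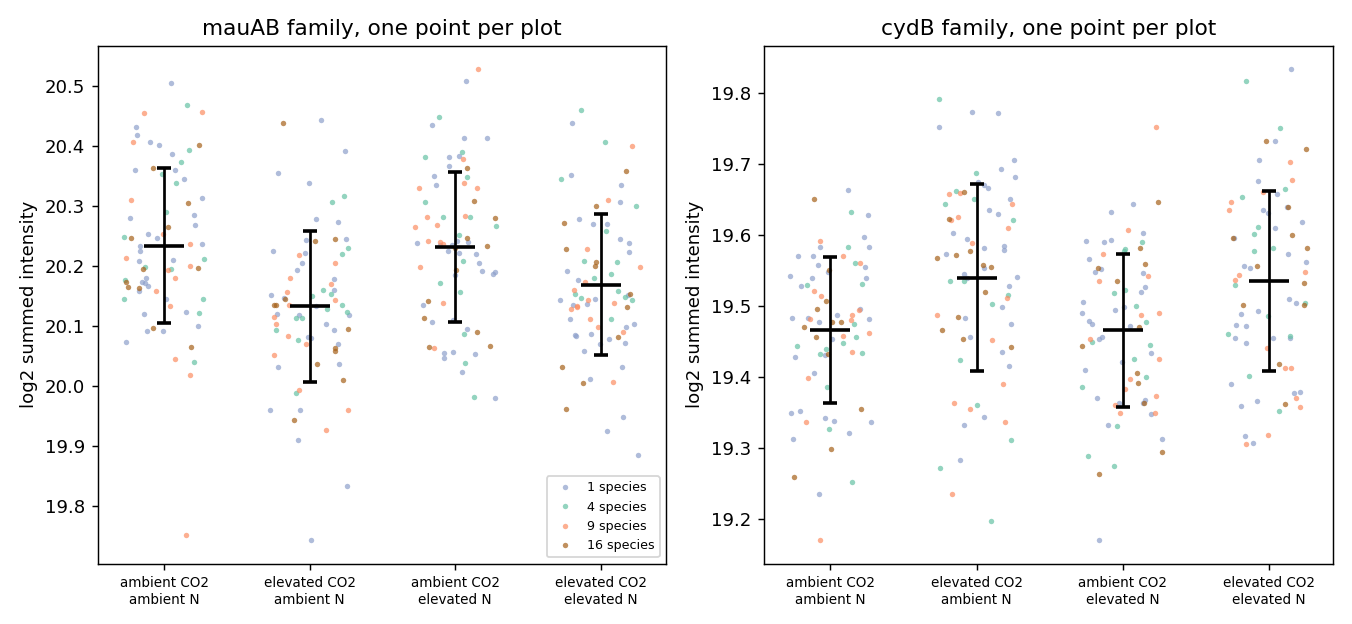
Each point is 1 plot's log2 summed intensity of mauAB or cydB by treatment, coloured by plant species number, and bars give the mean and SD (n = 74). Mean mauAB was 20.23 at ambient CO2 and N and 20.13 under elevated CO2, and mean cydB was 19.47 and 19.54.

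Among the 30 gene lists, 6 totals passed at ambient N, 3 higher and 3 lower (limma, Benjamini-Hochberg over the lists), against 1 with median scaling, 2 with the mean of member families and 3 without the 7 outlying arrays. Oxidative stress genes rose by 1.39% in total (95% interval 0.658 to 2.12, adjusted p = 0.00609). Of 6 tested members ahpC passed over all genes, and ahpC, ahpF and katA passed when adjusted over the list alone (3 members), while the other tested members did not. Sulfur cycling rose by 1.57% (adjusted p = 0.0392), where dsrB was the 1 of 4 tested members that passed over all genes and AprA and dsrB the 2 that passed adjusted over the list alone. Antibiotic resistance rose by 1.39% (adjusted p = 0.0413), with SMR_antibiotics the 1 of 11 members that passed both over all genes and adjusted over the list alone, although the median member changed by -0.00479 on the log2 scale. Hemicellulose degradation fell by 1.16%, dissimilatory nitrogen reduction by 2.08% and assimilatory nitrogen reduction by 2.35% (each adjusted p = 0.0413), and each of these 3 turned positive with median scaling. Their members past the threshold were xylA (1 of 5) and NiR (1 of 4), each also the 1 that passed adjusted over the list alone, while of the 2 dissimilatory members 0 passed over all genes (limma, nrfA at -2.52% with an unadjusted p = 0.0201) and 1, nrfA, adjusted over the list alone. With position blocks as a random block, the adjusted p was 0.990 for each of the 6 lists.

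Other lists of the nitrogen and carbon cycles did not pass at ambient N. nifH, the marker gene of nitrogen fixation, changed by 2.34% (95% interval 0.125 to 4.60, limma adjusted p = 0.178), and as the only member of its list it passed adjusted over the list alone. The ammonia oxidation gene amoA changed by 0.462% (adjusted p = 0.831), the nitrate reductase gene narG by -1.17% (adjusted p = 0.228), the urease gene ureC by 0.583% (adjusted p = 0.660) and the methanogenesis gene mcrA by -1.82% (adjusted p = 0.601). Among plant polymer genes, lignin degradation changed by 1.56% (adjusted p = 0.0997), cellulose degradation by 1.38% (0.290), chitin degradation by -0.858% (0.347) and starch degradation by 0.0906% (0.993). Of the table's own 10 carbon subcategories, 3 passed (limma). Among them were Cellulose at 1.93% (494 probes, adjusted p = 0.0215) and Hemicellulose at -1.16% (adjusted p = 0.0257), each at 0.781 with position blocks as a random block. The Cellulose subcategory holds more probes than the cellulose degradation list, whose members had 172, 130 and 140. Its p was adjusted over 10 totals, and that of the list over 30.

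**Figure D2:**
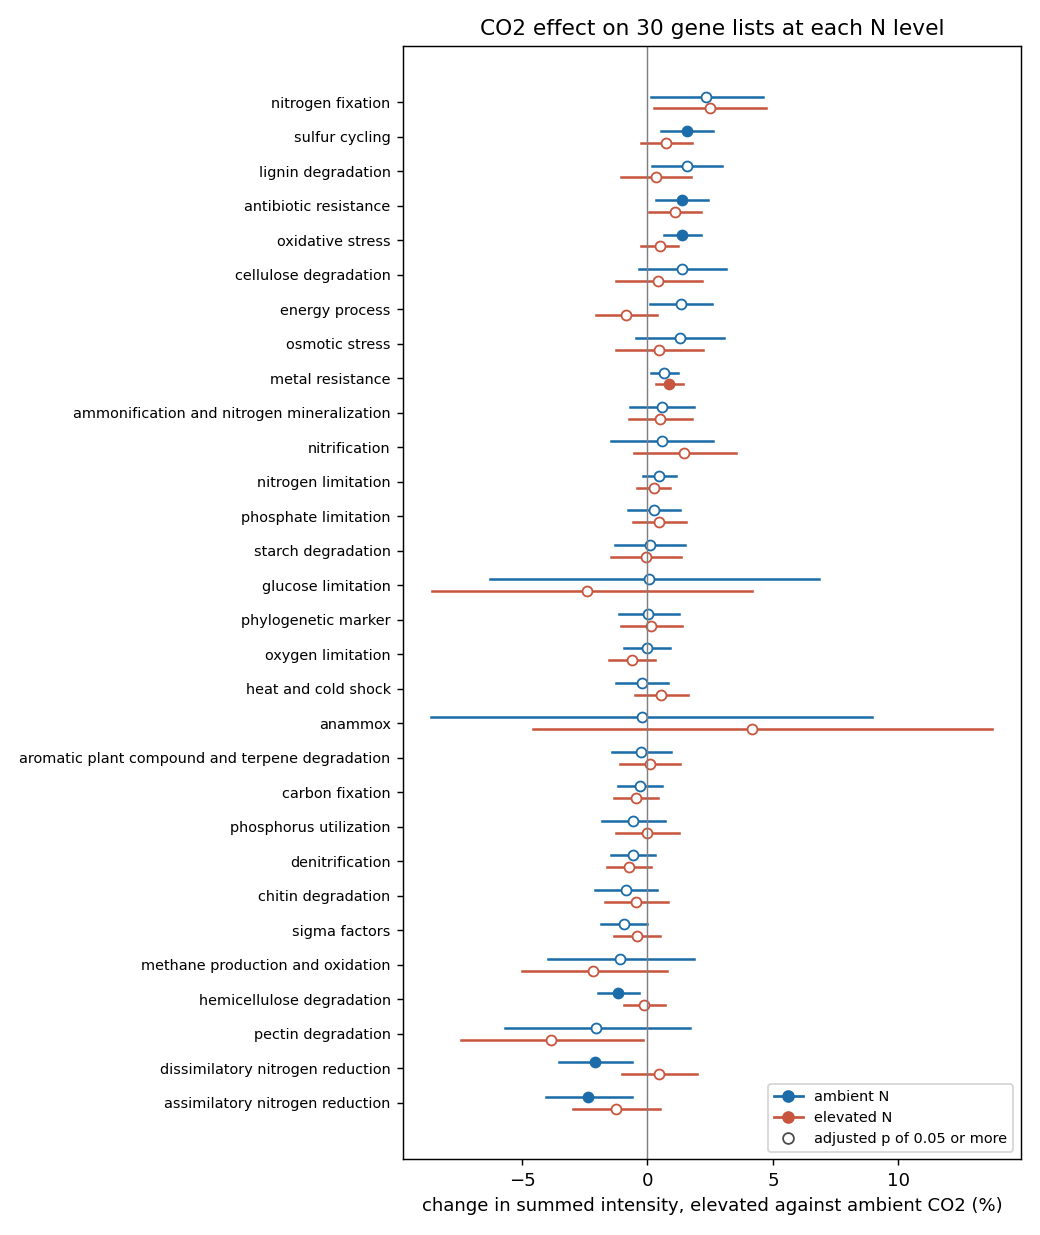
Percent change in summed intensity of 30 gene lists under elevated CO2, with 95% intervals, at ambient N and at elevated N (n = 74 plots per treatment). Filled points passed an adjusted p of 0.05, as 6 lists did at ambient N and 1 at elevated N, and the falls at ambient N turned positive with median scaling.

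At the level of single probes, falls outnumbered rises for CO2 at ambient N, but part of this was a shift of probes in general that depended on scaling. The median change over the 28649 tested probes was -0.0470 on the log2 scale, and 0.00595 with median scaling. Of 28649 probes, 1583 passed for CO2 at ambient N, 185 higher and 1398 lower (limma, Benjamini-Hochberg), against 164 higher and 278 lower with median scaling and 141 higher and 766 lower without the 7 outlying arrays. In the mauAB family 7 of 54 tested probes were lower and 0 higher, in nitA 17 of 144 were lower and 0 higher, and in vanA 11 of 149 were lower and 2 higher. With position blocks as a random block, 0 of the 28649 probes passed.

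The second CO2 comparison used the plots at elevated N, which share no array with the first. Elevated CO2 there went with less mdlB, a mandelate dehydrogenase gene, at 0.0536% ± 0.00589 of the signal (SD, n = 74) against 0.0490% ± 0.00632 (n = 74), a change of -8.86% (limma adjusted p = 0.00907). cydB rose by 4.90% (95% interval 2.15 to 7.72, adjusted p = 0.0431), close to its rise at ambient N. The chromate transporter gene ChrA rose by 2.52% (1.15 to 3.92, adjusted p = 0.0430), but changed by -0.000798 on the log2 scale after quantile normalization. The cytochrome_bd family of 3 probes fell by 20.2% (adjusted p = 0.0371). These 4 of 393 families passed, 2 higher and 2 lower, and 71 had an unadjusted p under 0.05. mauAB changed by -4.25% (adjusted p = 0.0777) and dsrB by 1.88% (adjusted p = 0.238). Of the 30 lists, metal resistance alone passed, with a total higher by 0.868% (adjusted p = 0.0391). ChrA was the 1 of its 30 tested members past the threshold over all genes, and 5 passed adjusted over the list alone, 4 higher and 1 lower. With position blocks as a random block, 0 families passed, with adjusted p = 0.996 for cydB and for mdlB, and the adjusted p of the metal resistance list was 0.986. Median scaling gave 0 families although the changes stayed as they were (mdlB -0.134 on the log2 scale with adjusted p = 0.149, cydB 0.0691 with adjusted p = 0.996), quantile normalization 0 higher and 6 lower, and no scaling 0 higher and 2 lower.

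Of the 28649 probes, 664 passed for CO2 at elevated N, 147 higher and 517 lower (limma, Benjamini-Hochberg). With median scaling 77 were higher and 307 lower, and 0 passed with position blocks as a random block. The nitrate reductase family narG had 17 of 559 tested probes lower and 4 higher. Probes called at both N levels numbered 191, all in the same direction, where 36.7 would be shared by lists from unrelated plots, although the same position blocks occur at both N levels. Across the 393 families, CO2 effects at the 2 N levels had Pearson r = 0.489 and Spearman rho = 0.517, and 71.2% had the same sign. Families are not independent replicates, and 100 relabellings of the treatments gave r from -0.377 to 0.456. Those relabellings ignore position: of the 9 other splits of the 6 blocks into 3 against 3, 8 gave a higher r, up to 0.954.

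N addition was asked about at each CO2 level. At ambient CO2, the family with the smallest p was cytochrome, a set of electron transport genes, at 2.67% (95% interval 0.998 to 4.36, limma adjusted p = 0.668). It was followed by the biphenyl degradation gene bphB at 14.6%, mdlB at 6.06%, the osmoprotectant uptake gene proX at 7.71% and phdJ at 17.7% (each adjusted p = 0.670). None of these passed: 0 of 393 families did (limma), with 20 at an unadjusted p under 0.05. Nitrogen cycle genes were among those that did not pass, such as amoA at -0.743% (adjusted p = 0.904), nifH at 0.676% (0.904) and ureC at -1.05% (0.808). At elevated CO2 the smallest p-values were those of single_strand_annealing_protein of phages at 13.7% (adjusted p = 0.434), and of 4HBH at 5.04%, phdA at -19.5%, merB at 3.68% and tphB at 26.5% (each adjusted p = 0.984). There 0 of 393 families passed (limma), with 15 at an unadjusted p under 0.05. Over single probes, 0 of 28649 passed at either CO2 level, with 1496 at ambient and 1069 at elevated CO2 at an unadjusted p under 0.05.

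Totals of the 30 lists gave 0 calls for N at either CO2 level. Over the table's own categories, Energy process, which holds cytochrome and hydrogenase genes, was higher under N at ambient CO2 by 1.81% (95% interval 0.646 to 2.98, limma adjusted p = 0.0297, and 0.0201 with position blocks in the fit). The call was lost without the 7 outlying arrays, where the change was smaller at 1.22% (adjusted p = 0.341), and with median scaling, where it was larger at 6.08% (adjusted p = 0.146) but its standard error went from 0.00839 to 0.0387 on the log2 scale. N effects across families at the 2 CO2 levels had Pearson r = -0.0495 and Spearman rho = -0.0845 over 393 families, and 100 relabellings gave r from -0.524 to 0.473, 65 of them at least as high.

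The interaction asks whether CO2 acts differently at ambient and at elevated N. The smallest p-values were those of cytochrome at -3.47% (95% interval -5.68 to -1.21) and of integrase_tyrosine at 11.2%, the triazine degradation gene atzC at -4.31%, proX at -10.1% and phdJ at -20.6%, each with a limma adjusted p = 0.696. None of the 393 families passed, with 17 at an unadjusted p under 0.05, and 0 of 28649 probes passed, with 1595 at an unadjusted p under 0.05 (limma). For cydB the interaction was -0.289% (95% interval -3.96 to 3.52, adjusted p = 0.976) and for mauAB 2.73% (-1.25 to 6.87, adjusted p = 0.925). A difference between the CO2 effects at the 2 N levels was thus not shown for any family. The Energy process category was the only total that passed, at -2.39% (-3.96 to -0.794, adjusted p = 0.0460, and 0.0320 with position blocks in the fit). That call was lost without the 7 outlying arrays, at -1.70% (adjusted p = 0.324), and with median scaling, at -6.88% (adjusted p = 0.254) with a standard error of 0.0547 against 0.0119 on the log2 scale.

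With CO2 and N both elevated against both ambient, atzB, a gene of the breakdown of the herbicide atrazine, fell by 4.41% (95% interval -6.52 to -2.25, limma adjusted p = 0.0332). It was the 1 family of 393 that passed, and 58 had an unadjusted p under 0.05. cydB changed by 4.83% (2.09 to 7.65, adjusted p = 0.103), mauAB by -4.43% (adjusted p = 0.121) and nifH by 3.17% (0.941 to 5.45, adjusted p = 0.185). No list passed, with 0 of 30 (limma). The Bacteria phage category was higher by 4.00% (1.68 to 6.36, adjusted p = 0.00882), against 3.90% (adjusted p = 0.982) with position blocks as a random block and 8.37% (adjusted p = 0.0552) with median scaling. Of single probes 119 passed, 14 higher and 105 lower, against 6 higher and 1 lower with median scaling and 0 with position blocks as a random block. The atzB change of -0.0651 on the log2 scale was -0.0648 with the random block (adjusted p = 0.997) and -0.00566 with median scaling (adjusted p = 0.919), where the 1 family past the threshold was another, and higher.

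Plant species number was the third factor, and plots with 16 species were set against plots with 1. Plots with 16 species held more of 3 genes that act on arsenic and mercury. aoxB, the arsenite oxidase gene, was higher by 5.15% (95% interval 2.68 to 7.68, limma adjusted p = 0.0160), with a mean log2 intensity of 19.69 ± 0.09 (SD, n = 48) at 16 species and 19.62 ± 0.10 (n = 128) at 1. merB, the organomercurial lyase gene, rose by 6.77% (adjusted p = 0.0430), and its mean went from 18.46 at 1 species to 18.52 at 4, 18.53 at 9 and 18.56 at 16. arsM, the arsenite methyltransferase gene, rose by 5.84% (adjusted p = 0.0439). These were the 3 of 393 families that passed, all higher, and 25 had an unadjusted p under 0.05. All belong to the metal resistance list, of whose 30 tested members 3 passed over all genes and 3 adjusted over the list alone, while the list's total changed by -0.139% (adjusted p = 0.950). With position blocks in the fit the adjusted p was 0.00633 for aoxB, 0.0280 for merB and 0.0354 for arsM. All 3 calls were lost with median scaling (adjusted p = 0.804), where aoxB went from 0.0724 to 0.0383 on the log2 scale, merB from 0.0944 to 0.0603 and arsM from 0.0819 to 0.0478, and with quantile normalization (0.738), no scaling (0.0954) and without the 7 outlying arrays (0.0681 for aoxB).

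Single probes showed larger differences with plant species number. Of 28649 probes, 40 passed (limma), 36 higher and 4 lower at 16 species, and 15 higher and 4 lower with median scaling. When undetected values, otherwise left out, were set to the lowest value of the array, 26 were higher and 10 lower. The probes named here were chosen after their values were seen, as those with the smallest adjusted p. A probe for the tellurium resistance gene TerZ of Nocardioides had a mean log2 intensity of 13.14 ± 0.39 (SD, n = 117 plots with a signal) at 1 species, 13.50 at 4, 13.63 at 9 and 13.75 ± 0.37 (n = 48) at 16, a fitted rise of 0.61 (limma adjusted p = 3.09e-10). A probe for a phage single_strand_annealing_protein rose by 0.61 (adjusted p = 6.55e-10). A probe for pcaG of Ralstonia, a subunit of the protocatechuate dioxygenase that opens aromatic rings, rose by 0.71 (adjusted p = 1.87e-09), from 13.17 ± 0.47 (n = 110) to 13.88 ± 0.53 (n = 48). Probes for Catechol of Chromohalobacter (0.61, adjusted p = 1.68e-08), pimF of Nocardioides (0.47, adjusted p = 1.12e-07) and pheA of Arthrobacter (0.43, adjusted p = 1.37e-06) followed. The 40 probes belonged to 34 gene names and 26 named genera, and 29 of the 36 rising probes had means that rose at each step from 1 to 4, 9 and 16 species. The choice of probes by their difference between 16 and 1 species favours such an order. No count expected from that choice was made, so a graded response was not tested. With position blocks in the fit all 40 passed again, among 65 probes in total, and 17 of the 40 passed with median scaling.

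Whether treatment effects differed between plant species numbers was tested with a moderated F test. The smallest p was that of ATP_binding_protein_related_resistance (adjusted p = 0.467), followed by MSAD and silP (each adjusted p = 0.999). None of the 393 families passed (limma), and 9 had an unadjusted p under 0.05.

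Over all probes, CO2 accounted for 1.16% of the variation in Bray-Curtis distance (permutation p = 9e-04, which takes no account of position). N accounted for 0.347% (p = 0.364), the CO2 by N interaction for 0.380% (p = 0.281) and plant species number for 0.773% (p = 0.862). Spread within treatments did not pass its test (permutation p = 0.104). The 6 position blocks accounted for 19.05% of the variation (p = 1e-04, the smallest the permutations could give), with 17.5% among the 3 blocks at ambient CO2 and 18.7% among the 3 at elevated CO2. Within 1 CO2 level, N accounted for 0.896% (p = 0.0866) at ambient and 0.581% (p = 0.354) at elevated CO2. Each of the 9 other splits of the 6 blocks into 3 against 3 gave a share at least as large as that of CO2, up to 10.3%, so the p for CO2 does not set it apart from position.

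**Figure D3:**
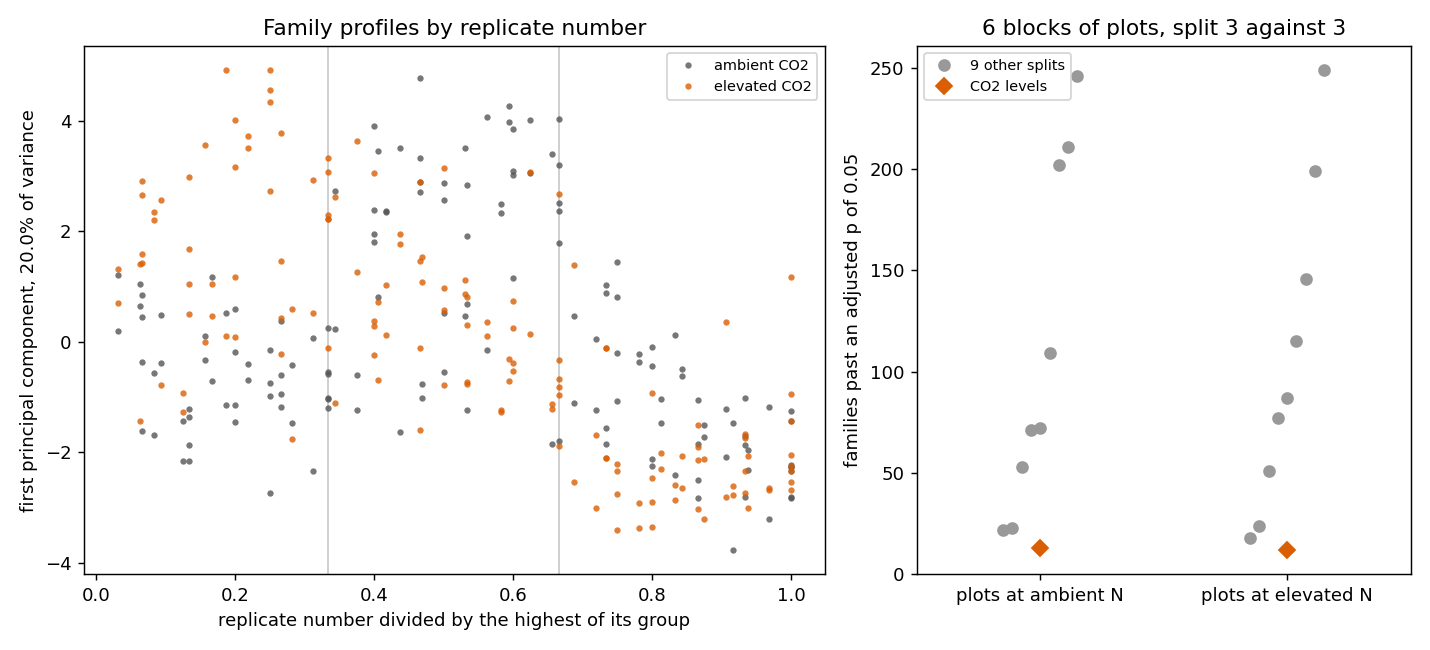
Left, the first principal component of family profiles (20.0% of variance) for each plot against its replicate number relative to the highest of its group; right, the number of families past an adjusted p of 0.05 for each 3 against 3 split of the 6 position blocks. At ambient N the split by CO2 gave 13 families and the other splits 22 to 246, and at elevated N it gave 12 against 18 to 249.

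Totals by domain asked whether bacterial, archaeal or fungal probes shifted as a whole. Fungal probes changed by 1.78% under elevated CO2 at ambient N (95% interval 0.267 to 3.32, limma adjusted p = 0.105) and by 0.776% at elevated N (adjusted p = 0.388). Archaeal probes changed by -0.505% (adjusted p = 0.666) and 0.692% (adjusted p = 0.557), and bacterial probes by -0.0752% (adjusted p = 0.146) and -0.0678% (adjusted p = 0.263). None of the 5 domain classes passed for CO2, for N, for the interaction or for plant species number (limma), while 1 class, the probes given no domain, was higher by 2.60% with CO2 and N both elevated (adjusted p = 0.0243, and 0.816 with position blocks as a random block). At an unadjusted p under 0.05 there was 1 class, fungi, for CO2 at ambient N, and 2 classes for CO2 at elevated N.

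Shannon diversity of probe intensities was lower under elevated CO2 at elevated N, by a mean difference of -0.0398 (9.85 ± 0.0819 at ambient CO2 against 9.81 ± 0.0745, SD, n = 74 each, permutation test adjusted p = 0.0174 over 7 contrasts), a call lost with position blocks as a random block (-0.0400, adjusted p = 0.407). At ambient N the difference was -0.0217 (adjusted p = 0.279), and -0.0421 (adjusted p = 0.0056) without the 7 outlying arrays, 5 of which belong to plots at ambient CO2 and N. Under N at ambient CO2 it was 0.0383 (adjusted p = 0.0750, and 0.0333 with the random block), and 0.0179 (adjusted p = 0.282) without the 7 arrays. The number of detected probes did not pass the permutation test for any contrast. Its largest difference was 975 more probes under N at ambient CO2 (permutation p = 0.0289, adjusted p = 0.202, and 0.0305 with the random block), and 388 without the 7 arrays (adjusted p = 0.407).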

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

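The tests of explanations in this part were chosen before their results were seen. The fits of the category without the 7 outlying arrays and with median scaling were chosen after the data were seen. The Energy process category total was singled out because its interaction of CO2 and N passed, at -2.39% (95% interval -3.96 to -0.794, limma adjusted p = 0.0460). The call was lost without the 7 outlying arrays (-1.70%, adjusted p = 0.324) and with median scaling (-6.88%, adjusted p = 0.254). The category's mean log2 intensity was 22.44 ± 0.06 (SD, n = 74) at ambient CO2 and N, 22.46 ± 0.05 under elevated CO2, 22.46 ± 0.05 under elevated N and 22.45 ± 0.04 under both.

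A linear effect of detected probes is argued against as the whole cause, since the interaction was still -2.04% with detected probes per array as a covariate. A covariate cannot exclude that a few outlying arrays carry part of the interaction. Without the 7 outlying arrays, 5 of them from plots at ambient CO2 and N, it was -1.7% (limma adjusted p = 0.324). The cytochrome family carried 68.6% of the category's signal, and without it the interaction was 0.0692% (limma adjusted p = 0.950), so the size of the pattern rests on that family. Without Ni_Fe_hydrogenase the interaction was -2.26%, and the call was lost as well (adjusted p = 0.0911). Without hydrogenase or without P450, the category's other families, it still passed. Neither cytochrome itself (-3.47%, adjusted p = 0.696) nor Ni_Fe_hydrogenase (-6.56%, adjusted p = 0.925) passed. Chance is not excluded, because 8 of 100 splits of the arrays, the real one counted, put at least 1 category past the threshold for the interaction, and the highest other split gave 2. A biological response of the cytochrome genes to N that differs by CO2 level stays open as an untested explanation.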

How the results depend on the processing

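The fits with position blocks, the list, probe, composition and agreement fits without 7 outlying arrays, and the alternatives for categories and phyla were chosen after the data were seen. Named families, categories and phyla past the threshold were compared with 429 alternative values: 198 kept direction and call, 216 kept direction without the call, and 15 reversed. Of 2748 such values for results that did not pass, 12 came to pass. The cause was not tested except where stated. The field ring of each plot is not given in the sources used here, so plots were treated as independent.

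Median scaling raised all families for CO2 at ambient N, by a median of 0.0679 on the log2 scale (lowest 0.0109, highest 0.0852), which is the cause of the reversals there: carA 0.00347, nitA 0.00695, ohbAB 0.00736, bphC 0.0118, vanA 0.0385, xylA 0.0288, the Organic Remediation category 0.0579 and Actinobacteria 0.0533 (0.0445 for CO2 and N together). It gave 3 families for CO2 at ambient N (3 higher, 0 lower, none of the report's 20), 0 for CO2 at elevated N and 0 for plant species number. It gave 1 list for CO2 at ambient N, 1 for both treatments together and 0 for CO2 at elevated N, and 442, 7 and 384 probes for the same contrasts, with 19 for plant species number. Quantile normalization gave 0 families for CO2 at ambient N, 2 for N at ambient CO2, 0 for both together and 0 for plant species number, and ChrA for CO2 at elevated N became -0.000798. No scaling gave 33 families (28 higher, 5 lower, 11 of the 20 among them), 3 for both together, 2 for CO2 at elevated N and 0 for plant species number.

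The mean log2 over detected probes gave 4 families for CO2 at ambient N (2 of the 20 among them), 1 for N at ambient CO2, and 0 for both together, for CO2 at elevated N and for plant species number. With it, Ni_Fe_hydrogenase (-0.0569), cydB (-0.0591), SMR_antibiotics (-0.0318), ahpC (-0.0425) and dsrB (-0.0513) reversed for CO2 at ambient N. The mean of member families gave 2 lists for CO2 at ambient N, 1 for both together and 0 for CO2 at elevated N. Only probes detected on at least 50% of the arrays gave 0 families for both together and 0 for plant species number, and no filter gave 7 for CO2 at elevated N and 1 for plant species number. Detected probes as a covariate gave 32 families for CO2 at ambient N, among them all 20 of the report, and 11 at elevated N. Without the 7 arrays there were 14 families for CO2 at ambient N (11 of the 20 among them) and the same 4 at elevated N. There were 0 families for both together and 0 for plant species number, 3 lists and 907 probes for CO2 at ambient N, 49 probes for both together, and a Shannon difference of -0.0421 for CO2 at ambient N.

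Plots with 1 plant species only gave 4 families for CO2 at ambient N and 0 for both together and for CO2 at elevated N, and plots with 4, 9 or 16 species gave 0 for each of these 3. Only the arrays compared gave 13, 0 and 12 families. A linear trend over log2 of the plant species number gave 6. Position blocks as a random block (correlation 0.178 for families) gave 0 families, 0 lists and 0 probes for CO2 at either N level and 0 families and 0 probes for both together, since the blocks lie within CO2 levels. The Shannon difference for CO2 at elevated N was -0.0400 with it, no longer past the threshold since its standard error was 0.0302, while N at ambient CO2 came to pass for Shannon diversity (0.0383) and detected probes (975). As a factor they gave 65 probes for plant species number.

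The replicate block, plant species number and replicate number together, gave 23 families for CO2 at ambient N, including the same 20, with 3 for both together, 9 for CO2 at elevated N and 1 list for both together. Over all treatments the numbers pair the plots weakly at most: of 444 pairs of arrays with the same number, 195 correlated above 0.1, with a mean of 0.0836. Within 1 CO2 level the mean was 0.179 (87 of 148 pairs above 0.1) and across CO2 levels 0.0359. Within a group neighbouring numbers had 0.126, so resemblance by position may be part of it. A pairing of plots by number within 1 CO2 level is not ruled out. This block could not be fitted for plant species number, which it contains.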

Other observations

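The tests of resemblance by replicate number and of differences between position blocks by moved labels were chosen after the result was seen, as were the fits with position blocks and the alternatives for categories and phyla. Of 22 phylum totals, 4 passed for CO2 at ambient N and 7 at elevated N. Probes of Chlamydiae, obligate intracellular bacteria, were higher by 11.1% (95% interval 6.26 to 16.2, limma adjusted p = 0.000107, 69 probes) at ambient N and by 11.8% (6.90 to 16.9, adjusted p = 3.18e-05) at elevated N. Bacteroidetes were higher by 3.00% (adjusted p = 0.0285) and 3.65% (adjusted p = 0.00341), and Chloroflexi by 1.66% (adjusted p = 0.0113) and 1.39% (adjusted p = 0.0240). Actinobacteria were lower by -1.01% (adjusted p = 0.0113) and -1.35% (adjusted p = 0.000219), the former turning positive with median scaling. Fusobacteria (22.1%), Spirochaetes (10.1%) and Crenarchaeota (6.69%) also passed at elevated N, while 0 of 22 phyla passed for the interaction (limma, 0 at an unadjusted p under 0.05). With median scaling Chlamydiae (16.5%), Bacteroidetes (7.97%) and Chloroflexi (6.56%) passed at ambient N, and at elevated N Bacteroidetes (adjusted p = 0.301), Chloroflexi and Actinobacteria (each 0.897) did not. With position blocks as a random block none of the 22 phyla passed, with Chlamydiae still at 10.96% at ambient N (adjusted p = 0.891) and 11.6% at elevated N (adjusted p = 0.879), since the standard error went from 0.0326 to 0.0876 on the log2 scale.

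Among the table's own categories, Organic Remediation was lower by -0.691% (limma adjusted p = 0.00977) at ambient N, a sign that turned with median scaling, and by -0.747% (adjusted p = 0.00357) at elevated N. Metal Resistance was higher by 0.615% (adjusted p = 0.0421) and 0.857% (adjusted p = 0.00562). Sulphur (1.54%, adjusted p = 0.0164), Energy process (1.70%, adjusted p = 0.0172) and Antibiotic resistance (1.39%, adjusted p = 0.0263) were higher at ambient N, and Bacteria phage (3.07%, adjusted p = 0.0368) at elevated N. The interaction did not pass for Sulphur, Antibiotic resistance or Bacteria phage (each adjusted p = 0.845), and Energy process was -0.728% at elevated N (adjusted p = 0.387). With median scaling none of these categories passed for CO2: at ambient N Metal Resistance was 5.47%, Sulphur 6.43%, Energy process 6.61% and Antibiotic resistance 6.28% (adjusted p from 0.0778 to 0.0785), and at elevated N the 3 values stayed (each adjusted p = 0.998). Without the 7 outlying arrays Metal Resistance (0.561%), Sulphur (0.972%) and Energy process (1.12%) did not pass at ambient N (each adjusted p = 0.113). With position blocks as a random block these categories had adjusted p = 0.882 at ambient N and 0.987 at elevated N.

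The calls for CO2 were set against chance and against the position of the plots. Moving labels between arrays within plant species number breaks up the position blocks, so it tests chance only for plots taken as independent. On that footing chance is argued against for 20 families (2 of 100 splits as large, the real one counted here and below, highest other 80), 1583 probes (2 of 100, 5620) and 6 lists (2 of 100, 7) at ambient N. At elevated N the same holds for 4 families (3 of 100, 20) and 664 probes (2 of 100, 690), though not for its 1 list (6 of 100, 6). Single splits that called several times the real number point to a structure of the samples, though families and probes that vary together would also give them. Position, by field ring or processing order, is consistent with the calls: on plots split by block, 10 of 10 splits of the 6 blocks gave at least as many families as CO2 did at ambient N (13, highest other 246) and at elevated N (12, 249), and 9 of 10 gave an agreement of effects across N at least as high as the real r of 0.489, up to 0.954. A linear effect of detected probes per array is argued against as the whole cause, since 32, 11 and 1 families passed with them as a covariate. A covariate cannot exclude that a few outlying arrays carry part of the calls. Without the 7 outlying arrays, 14 families (11 of the 20 among them) and 907 probes passed at ambient N. An effect of CO2 thus stays open beside position and beside chance among whole blocks, which the block splits do not argue against.

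Plots differed strongly by replicate number within 1 CO2 level. The nearest array lay in the same position block for 66.2% of arrays, against 17.6% to 31.4% after relabelling, and 307 families at ambient CO2 and 310 at elevated CO2 differed between the 3 blocks. Chance is argued against (1 of 100 splits as large at each level, highest others 69 and 0). So is a linear effect of detected probes as the whole cause (259 and 271 families with them as a covariate). Soil differences between field rings and the order of laboratory work may each be the source, and the labels separate neither.

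For plant species number, chance is argued against for the 3 families (2 of 100 splits as large, highest other 6) and for the 40 probes (1 of 100, highest other 10), while the 0 lists are matched by all 100 splits (highest other 4). With CO2 and N together, 119 probes had 2 of 100 splits as large (highest other 133), the 1 family had 8 of 100 (highest other 7), and the 0 lists had 100 of 100 (highest other 2). For N at ambient CO2, the interaction and N at elevated CO2, the counts of 0 were matched by 100 of 100 splits, with highest others of 3, 65 and 8 families, 2, 4622 and 138 probes, and 2, 7 and 2 lists. For the F test of treatment by species number the highest other split gave 3 families, and 100 of 100 were as large. These 3 contrasts with N also gave 0 families with position blocks in the fit and 0 with detected probes as a covariate, values that decide nothing about either. Nor do the 10 of 10 splits of the position blocks for CO2 and N together (highest other 247), since the real count on the arrays compared was 0.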
